A study of Sorghum bicolor with 4 samples.

How the data were processed

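Stem RNA-seq libraries from the middle internode of the sweet sorghum line ICSA38 were compared between the milk stage (2 libraries) and physiological maturity (2 libraries). Per the labels' protocols, total RNA was isolated by a modified Trizol method and libraries were made with a stranded total RNA kit. Per the submitters' processing notes, cutadapt 1.8.1, Bowtie2 2.2.9, HISAT2 2.0.5 and Cuffdiff were used, with no version for Cuffdiff and no role for each tool. The genome build, the strand setting, the treatment of ribosomal reads and the scaling between libraries are not given in the sources used here.

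The FPKM values (fragments scaled to locus length and to the number of mapped fragments) were computed by the authors and deposited as 1 table of 34458 loci with 2 value columns, whose headings match the sample titles of each stage without the replicate number. They were taken as the authors' combined value per stage, with no standard deviation and no number of replicates. The labels number the libraries of each stage and do not say whether they came from separate plants. Of the loci, 31423 carry 1 Sobic gene identifier, 1262 carry several (up to 8) and 1773 carry none. For a locus with several identifiers the value cannot be assigned to any of its genes.

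The plan fixed before the data were examined was a limma test on log2(FPKM + 1) across the 4 libraries, with no test if the table held 1 value per stage. That was the case, so no test was run, and differences are described by size. The log2 difference was log2(maturity FPKM + 1) minus log2(milk-stage FPKM + 1). Loci were compared where the FPKM was at least 1 at either stage, in place of the planned minimum in at least 2 libraries, and a difference of at least 1 on the log2 scale (2-fold) was counted. The 2-fold limit without a p-value replaced the planned threshold after the table was seen to hold no replicates.

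Also planned were 35 gene lists defined by words in product descriptions. The table holds no descriptions, and 0 of its 34129 gene identifiers matched the reference gene table, so none of these lists could be formed, including the lists of markers for other cell types and tissues. The rule for named genes then left the 16 genes fixed by their published Sobic identifiers. Names of these genes come from that fixed list and not from the table, and their assignment to 4 groups by known function was made after the table was seen. In addition, among the loci with exactly 1 gene identifier, the 2 with the largest increase and the 2 with the largest decrease in FPKM units are given by identifier. No genome or annotation was used, so no coordinates are given. Each gene was placed among the 500 loci nearest to it in mean FPKM, and each group's median among the medians of 10000 random lists drawn from those loci.

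The number of sequenced fragments is unknown, and fragments could not be recovered from FPKM without the locus lengths. The low values show steps. Of 909 loci with a value above 0 and under 0.05 FPKM at both stages, 198 had a log2 ratio of maturity to milk stage between -0.33 and -0.22, against 7 and 3 loci in the adjoining ranges of the same width above and below. The median ratio of those 198 loci was 0.835. It is a median over a range that may mix several steps, since each value is taken to combine libraries whose depths are not known, and is not used as a ratio of depths. An FPKM of 0 is read as listed at 0.

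Alternatives were pseudocounts of 0.1 and 0.5, no filter, a minimum of 5 FPKM, quantile normalization, scaling to equal sums, median-of-ratios scaling, and, added after seeing the data, a 4-fold limit, plain ratios of loci at 1 FPKM or more at both stages, loci with 1 identifier and gene groups without their member of largest difference. The calculation was tested on simulated values for the comparison of maturity with milk stage, with 200 of 17585 loci changed and an assumed noise of 0.2 (SD, log2). It counted 98.0% of loci changed by 1.5 on the log2 scale, 100% of those changed by 2, and 0% of the unchanged loci. Changes were put only into loci at 5 FPKM or more at the milk stage, and no counting error was simulated. The 2-fold limit lies far above the assumed noise, so the 0% follows from that setting. These percentages check the calculation and give no error rate for the deposited values, whose spread between libraries is unknown. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.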

Results

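RNA was measured by sequencing in the middle stem internode of field-grown sweet sorghum of the line ICSA38, a type of sorghum whose stalk stores sugar. Internodes were taken at the milk stage of grain filling and later at physiological maturity, with 2 libraries per stage and 4 in all. The deposited table gives 1 FPKM value per locus and stage, taken from its headings to combine the libraries of a stage. The authors' values therefore carry no standard deviation, no comparison below has a test or a p-value, and whether a difference exceeds the spread between libraries cannot be read from them. Differences are given as log2 of maturity over milk stage after adding 1 to each FPKM, which understates the difference of low loci.

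The table lists 34458 loci. At an FPKM of at least 1, 17445 loci were expressed at the milk stage and 17681 at physiological maturity. Of these, 16377 were above that level at both stages, 1068 at the milk stage alone and 1304 at maturity alone. The values summed to 800834 FPKM at the milk stage and 666768 FPKM at maturity. The 10 most abundant loci held 9.71% of the sum at the milk stage and 7.15% at maturity, and the 100 most abundant held 26.0% and 19.9%. The number of fragments behind these sums is not given, so the counting error of each value is unknown.

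The question set by the design is how the transcripts of the middle internode differ between the stages. Of the 18749 loci with an FPKM of at least 1 at either stage, 2163 were at least 2-fold higher at maturity and 2011 at least 2-fold lower, together 22.3% of the loci compared. At least 4-fold differences were found for 416 loci in the upward and 427 in the downward direction. The median log2 difference over all loci compared was 0.04, with 25th and 75th percentiles of -0.48 and 0.57. The values of the stages correlated across loci with a Pearson r of 0.880 on the log2 scale and a Spearman rho of 0.877, a description across loci, which are not independent replicates. The split of higher and lower loci was near even as deposited and under quantile and median-of-ratios scaling (49.7% and 49.2% higher), but not with equal sums. When both stages were set to the same sum, the median of all loci moved up by 0.24 and 69.7% of the loci at least 2-fold apart were higher at maturity, against 51.8% as deposited. That sum was above the deposited sum of either stage. More loci, 19581, therefore passed the FPKM minimum and the pseudocount weighed less, so the shares are not of the same loci.

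**Figure D1:**
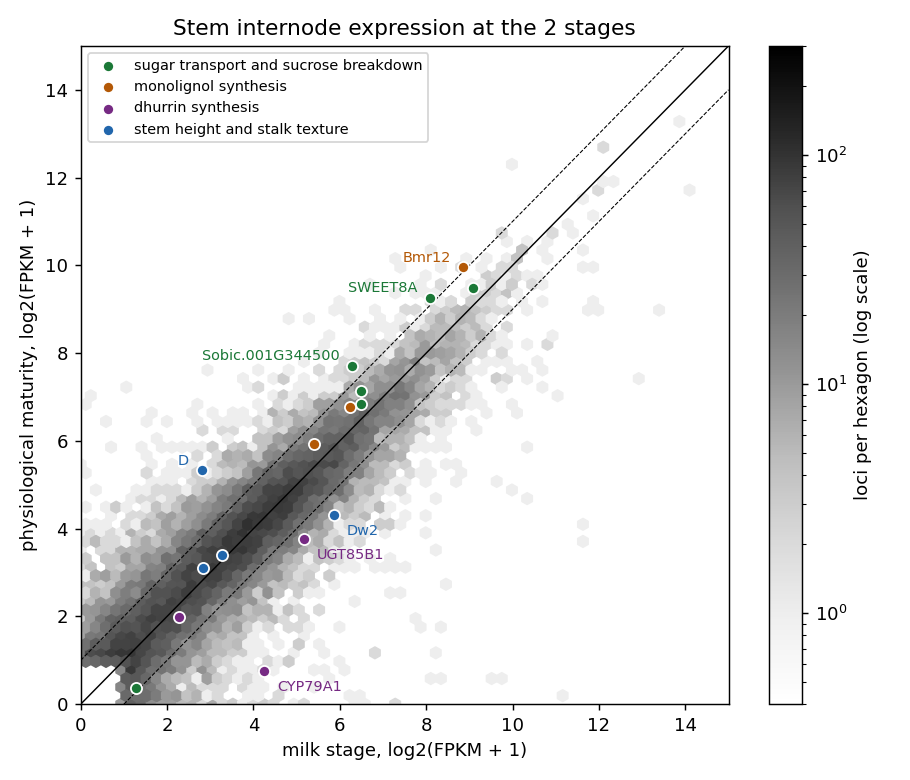
Expression at physiological maturity (y axis) against the milk stage (x axis), both as log2(FPKM + 1), for 18749 loci binned into hexagons. The solid line marks equal values, dashed lines a 2-fold difference, and coloured points the 16 genes chosen in advance, of which the 7 outside the dashed lines are labelled.

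Of 16 genes with known roles in stem sugar, lignin, cyanogenic glucoside and stem form, chosen by identifier before the data were examined, 11 had higher values at maturity and 5 lower. With a pseudocount of 1, a difference of at least 2-fold was seen in 4 of the higher and 3 of the lower genes, and the vacuolar invertase was a further lower gene past that limit with pseudocounts of 0.1 and 0.5. Each of these genes had a locus of its own in the table.

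Genes of sugar transport and sucrose cleavage were mostly higher at maturity, 5 of 6, of which 2 by at least 2-fold, with a median log2 difference of 0.53. SWEET8A (Sobic.008G094000), a member of the SWEET family of sugar carriers, was at 272 FPKM at the milk stage and 612 FPKM at maturity, 2.25-fold higher. The sucrose synthase gene Sobic.001G344500, whose enzyme cleaves sucrose reversibly, was at 77.2 and 209 FPKM, 2.68-fold higher, while the other sucrose synthase gene, Sobic.010G072300, was more abundant and closer between the stages at 543 and 720 FPKM. SUT1 (Sobic.001G488700), a sucrose-proton symporter, was at 88.3 and 139 FPKM, and TST2 (Sobic.004G099300), a sugar transporter of the vacuolar membrane, at 89.0 and 113 FPKM. The log2 differences of TST2 (0.35) and Sobic.010G072300 (0.40) lay between the 25th and 75th percentiles of all loci. The vacuolar invertase gene (Sobic.004G004800), whose enzyme hydrolyses stored sucrose, was low at both stages, with 1.43 FPKM at the milk stage and 0.286 FPKM at maturity, a log2 difference of -0.92 with a pseudocount of 1 and -1.99 with 0.1. Among the 500 loci ranked around each in abundance, 96.8% had a lower log2 difference than Sobic.001G344500, 93.4% than SWEET8A and 15.2% than the invertase gene. The invertase gene had a mean under 1 FPKM. Loci with such a mean passed the filter only by reaching 1 FPKM at 1 stage and lying below it at the other. Its 15.2% and its part in the random lists therefore come largely from loci that had to differ. They cannot show whether its decrease was unusual. The median of the 6 genes lay above those of 97.6% of 10000 random lists matched on abundance, which describes these libraries and is not a test of the stages. The median was 0.82 with quantile normalization and 0.40 without Sobic.001G344500, and the central 95% of the random lists of 6 ended at 0.52, just below the reported 0.53.

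The 3 genes of monolignol synthesis, the pathway to the building blocks of lignin, had higher values at maturity, 1 of them by at least 2-fold, with a median log2 difference of 0.53. Bmr12 (Sobic.007G047300), the caffeic acid O-methyltransferase of the brown midrib loci, was at 463 FPKM at the milk stage and 997 FPKM at maturity, 2.15-fold higher. Bmr2 (Sobic.004G062500), a coumarate-CoA ligase, was at 74.5 and 108 FPKM. Bmr6 (Sobic.004G071000), a cinnamyl alcohol dehydrogenase, was at 41.1 and 59.9 FPKM, and both of these were about 1.45-fold higher. The log2 differences of Bmr2 and Bmr6, 0.53 each, lay between the 25th and 75th percentiles of all loci. Among the 500 loci ranked around each in abundance, 92.8% had a lower log2 difference than Bmr12, 84.6% than Bmr2 and 82.2% than Bmr6. For Bmr12 these were the 500 most abundant loci compared, most of them less abundant than Bmr12. The median of the 3 genes exceeded those of 93.5% of the matched random lists and lay inside their central 95% (-1.41 to 0.84).

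The 3 genes that make dhurrin, the cyanogenic glucoside of sorghum, were lower at maturity by different amounts, with a median log2 difference of -1.41, or -0.85 without CYP79A1. CYP79A1 (Sobic.001G012300), which catalyses the entry step from tyrosine, was at 18.1 FPKM at the milk stage and 0.691 FPKM at maturity, 11.3-fold lower after adding 1 to each value and 26.1-fold lower as a plain ratio. UGT85B1 (Sobic.001G012400), the glucosyltransferase of the final step, was at 35.1 and 12.6 FPKM, 2.65-fold lower. CYP71E1 (Sobic.001G012200), which acts between them, was at 3.84 and 2.98 FPKM, a log2 difference of -0.28 that 31.2% of the loci of similar abundance lay below. Only 0.2% of the loci of similar abundance had a lower log2 difference than CYP79A1, and 3.4% than UGT85B1. The median of the 3 genes lay above those of 0.81% of the matched random lists.

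Genes of stem height and stalk texture differed in direction. D (Sobic.006G147400), the NAC transcription factor gene of the dry stalk locus, was at 5.96 FPKM at the milk stage and 39.3 FPKM at maturity, 5.78-fold higher, and 99.2% of the loci of similar abundance had a lower log2 difference. Dw2 (Sobic.006G067700), a dwarfing locus that encodes a protein kinase, was at 57.6 and 18.8 FPKM, 2.95-fold lower. Dw1 (Sobic.009G229800), another dwarfing locus, was at 8.65 and 9.52 FPKM. Dw3 (Sobic.007G163800), which encodes an auxin efflux transporter, was at 6.15 and 7.63 FPKM. The log2 differences of Dw1 and Dw3 were 0.13 and 0.27, within the central range of all loci.

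**Figure D2:**
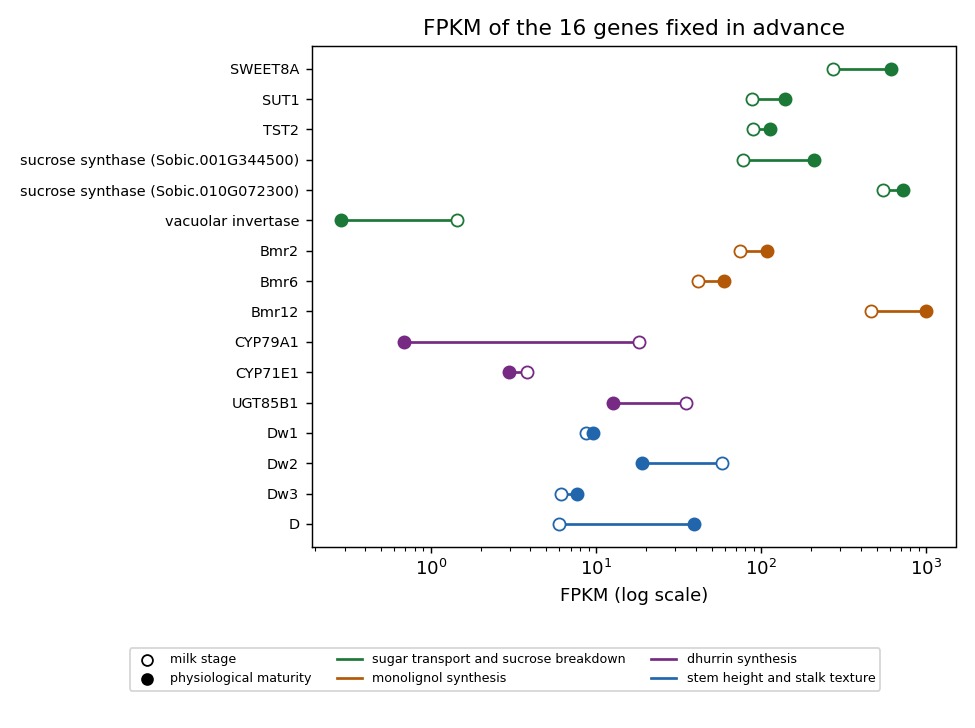
FPKM of the 16 genes chosen in advance (x axis, log scale) at the milk stage (open circles) and physiological maturity (filled circles), coloured by group, with 1 value per gene and stage and so no error bars. D lies furthest to the right of its milk-stage value, 5.96 against 39.3 FPKM, and CYP79A1 furthest to the left, 18.1 against 0.691 FPKM.

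The direction of the difference varied with abundance. Among the 6262 loci with a mean of 5 to 20 FPKM, 13.0% were at least 2-fold higher at maturity and 8.83% at least 2-fold lower, with a median log2 difference of 0.10. Among the 1149 loci at 100 to 500 FPKM, 7.05% were higher and 17.7% lower, with a median of -0.23. Among the 153 loci at 500 FPKM and above, 12 were higher and 43 lower, with a median of -0.34. Scaling moved these medians. With equal sums they were 0.35 at 5 to 20 FPKM, 0.03 at 100 to 500 FPKM and -0.08 from 500 FPKM, and quantile normalization, which forces the distributions to be alike, gave 0.02, 0.01 and 0.12. Median-of-ratios scaling left them near the deposited ones, at 0.07, -0.27 and -0.38. At 100 to 500 FPKM, 10.1% of the loci were higher and 11.7% lower with equal sums, and 9.92% and 12.6% with quantile normalization, a split closer to even than as deposited. With median-of-ratios scaling it was no closer to even, at 6.70% higher and 18.2% lower. At 500 FPKM and above, lower loci outnumbered higher loci under each scaling, by 37 to 13 with equal sums, 33 to 18 with quantile normalization and 45 to 12 with median-of-ratios scaling. The abundance ranges were set once from the deposited means and kept under each scaling. These counts therefore share 1 choice of loci and do not show the split in ranges drawn from rescaled values. The largest decrease in FPKM units among loci with exactly 1 gene identifier was that of Sobic.001G141300, the most abundant locus at the milk stage, at 17518 FPKM against 3380 FPKM at maturity. The next largest was that of Sobic.001G012500, numbered next to UGT85B1, at 11285 and 524 FPKM, 21.5-fold lower. Among the same loci with exactly 1 gene identifier, the largest increases were those of Sobic.009G197300, from 1062 to 5208 FPKM, and of Sobic.003G442900, from 294 to 1257 FPKM. The table does not pair these identifiers with gene names, and they were chosen after their values were seen.

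**Figure D3:**
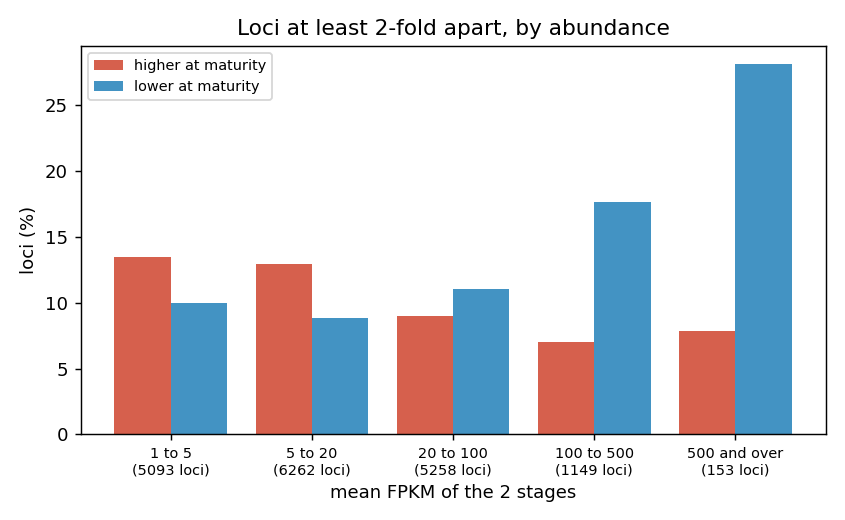
Percent of loci (y axis) at least 2-fold higher (red) or lower (blue) at physiological maturity, by the mean deposited FPKM of the stages (x axis, number of loci in parentheses). With the deposited scaling, the red bar exceeds the blue bar up to 20 FPKM, and above 500 FPKM 28.1% of the loci were lower against 7.84% higher (24.2% and 8.50% with equal sums, 21.6% and 11.8% with quantile normalization); 834 compared loci with a mean under 1 FPKM are not drawn.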

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

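With equal sums 3562 loci were higher at maturity, 69.7% of those apart, against 2163 and 51.8% as deposited. Equal sums raised the values of both stages, so 19581 loci passed the FPKM minimum against 18749 as deposited, and these counts come from different sets of loci. Under the quantile and median-of-ratios scalings, the pseudocounts of 0.1 and 0.5, the 5 FPKM minimum, plain ratios and loci with 1 identifier (these last 2 chosen after seeing the data), the counts stayed within 1.5 times those reported and the split between 49.2% and 54.1%. Plain ratios were counted only over the 16377 loci at 1 FPKM or more at both stages, which leaves out loci past that level at 1 stage alone. Leaving out the filter cannot add a call, since a locus under 1 FPKM at both stages cannot reach a log2 difference of 1 with a pseudocount of 1. A 4-fold limit, also chosen after seeing the data, left 843 loci, 416 higher and 427 lower. The 16 fixed genes kept their sign in 80 of 80 values under 5 alternatives (2 pseudocounts and 3 scalings), and 2 of those values moved by 0.58 or more, CYP79A1 to -4.52 and the vacuolar invertase to -1.99, both with a pseudocount of 0.1. A pseudocount cannot change the sign of a gene. Median-of-ratios scaling shifted the median of all loci by -0.03, less than the smallest difference of the 16 genes (0.13, Dw1). Equal sums raised maturity relative to the milk stage, which cannot turn a higher gene lower. Its upward shift of 0.24 was smaller in size than the smallest decrease of the 5 lower genes (-0.28, CYP71E1). The kept signs therefore bear mainly on quantile normalization. The vacuolar invertase passed the 2-fold limit with pseudocounts of 0.1 and 0.5 and not with 1. The medians of the 4 gene groups kept their sign throughout, but some moved by over 1.5 times. That of stem height and stalk texture (0.20) was 0.07 with quantile normalization, 0.45 with equal sums and 0.13 without D. That of the sugar genes (0.53) was 0.82 with quantile normalization and 0.79 with equal sums. That of the dhurrin genes (-1.41) was -0.85 without CYP79A1, and leaving out members was added after seeing the data. No paired analysis was possible because the table holds 1 value per stage. For the same reason the planned fits without each library, the other variance models, the count models and the gene set tests were not run, and the effect of any 1 library is unknown. Depth is unknown, which limits the reading of low values such as those of CYP71E1 and the invertase gene.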

Other observations

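Of the tests in this part, that on the correlation of neighbouring loci was set out before its result was seen, and the other 3 were chosen after the main values were known.

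Loci without a gene identifier held 1.78% of the FPKM sum at the milk stage and 2.57% at maturity. Of the 1005 that were compared, 29.2% were at least 2-fold apart, 159 higher and 134 lower at maturity, against 22.0% of the 16568 loci with 1 identifier. These shares were not matched on abundance, with which the share of loci at least 2-fold apart varied. Loci listed at 0 at one stage and at 5 FPKM or more at the other numbered 18 with the 0 at maturity and 8 with the 0 at the milk stage. By the chromosome number in the identifier, the share of loci at least 2-fold higher at maturity ran from 9.79% on chromosome 9 to 15.3% on chromosome 5.

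The lower values of the dhurrin genes at maturity sat beside those of Sobic.001G012500, the locus numbered after UGT85B1, which was far more abundant. The loci numbered around them were lower too at Sobic.001G012600 (144 and 50.7 FPKM) and Sobic.001G012100 (18.6 and 12.1 FPKM). Beyond these, Sobic.001G012800 (3.33 and 6.37 FPKM) and Sobic.001G012000 (0.448 and 6.41 FPKM) were higher. The 3 other scalings between the stages do not account for the lower values of CYP79A1 and UGT85B1, whose highest log2 difference under them was -1.17. These scalings moved the median of all loci by 0.24 at most. Shifts of that size could not remove differences of -3.50 and -1.41, so a larger scaling error was not tested. For CYP71E1 scaling stays open, since its difference of -0.28 went to -0.085 with equal sums. Reads of the abundant neighbour counted on the dhurrin genes remain open. The value of CYP79A1 was 0.160% of the neighbour's at the milk stage and 0.132% at maturity. Those of UGT85B1 were 0.311% and 2.41%, and those of CYP71E1 0.0340% and 0.568%, so a fixed share of the neighbour's reads cannot make up the whole values of UGT85B1 and CYP71E1, while it could still add to their milk-stage values. Such reads cannot make a gene decline by a larger factor than the neighbour, and the plain log2 ratio of CYP79A1 lay 0.28 below it (a difference of -0.28), but without a spread between libraries that margin cannot be judged. A lower expression of the pathway at the later stage is the difference the design names; it stays an untested hypothesis, as does a difference between the plants sampled.

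Stage differences of compared loci next to each other in identifier order were weakly correlated across loci. Loci left out of this order, such as those under the FPKM minimum or with several identifiers, can lie between them. Members of a pair therefore need not have adjacent identifiers or touch. Pearson r was 0.0909 over 16530 pairs next to each other in this order, and the highest of 100 shuffles within chromosomes gave 0.0199. At a distance of 2 places in the order r was 0.0293, against a highest shuffle of 0.0223. At 5 places it was -0.0024, inside the shuffled range, and at 10 places 0.0205, against a highest shuffle of 0.0192. A candidate explanation is reads or assembled transcripts shared between touching loci. The values inside the shuffled range at 5 places (-0.0024), 20 (-0.00045) and 50 (0.0025) go with it. They would go equally with any other cause limited to close neighbours, so they do not favour it. Those above the range at 2 places (0.0293) and 10 (0.0205) do not go with shared reads or transcripts. Which pairs touch is also unknown without coordinates, so this explanation stays open. Tandem gene copies and shared regulation of close neighbours also stay open and were not tested, since no sequences or coordinates were used.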
